A study of Mus musculus with 12 samples.

How the data were processed

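RNA-seq libraries of total RNA from 12 mouse livers were compared. Per the labels' protocols, the mice were kept on a diet named HFD for 12 weeks, the livers were flushed with buffer before extraction, and RNA libraries followed a standard Illumina protocol. Per the labels, 6 mice were Apoe-/- (here called controls) and 6 were Apoe-/-AhR-/- (here called Ahr-null), with 3 males and 3 females of each genotype. Replicate numbers follow accession order and only name the samples, so they pair nothing across groups. Each sample was taken as a separate mouse, as the labels give 1 liver per sample.

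The deposited count table holds raw whole-number counts per gene, with 1 column for each library. It has 27304 genes named by Ensembl ID, Entrez ID and symbol, of which 7277 had no count in any library. The authors also deposited variance-stabilised values on a scale close to log2, made with DESeq2 per the file headers. Per the submitters' processing notes, the tools were FastQC 0.11.8, Trim Galore 0.6.5, STAR 2.7.8 and DESeq2 1.28.1, with the mouse genome build GRCm38. The read counter, its strand setting and the annotation release are not given in the sources used here. Members of near-identical families, overlapping genes and antisense genes are therefore reported as uncertain. Gene positions come from GENCODE annotation of GRCm38, matched by Ensembl ID for 27225 of the genes.

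Genes were tested with edgeR 4.0.16 in R 4.3.3. Low-count genes were removed with filterByExpr by the 4 groups, which left 13641 genes, and libraries were scaled by TMM. A quasi-likelihood model with robust estimation and a mean for each of the 4 groups was fitted over all 12 libraries, with 8 residual degrees of freedom. The common dispersion was 0.129 and the median prior degrees of freedom were 4.85. There were 6 contrasts: the genotype effect averaged over sexes, the genotype effect in males, the genotype effect in females, the difference between those effects (the interaction), and the sex difference within each genotype. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are Ahr-null minus control or male minus female on the log2 scale. Levels are CPM, the counts scaled to a common total per library, after TMM scaling, as mean ± SD of 3 libraries, and standard errors come from the fold change and its F statistic.

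In all, 34 gene lists with 531 members were fixed before the data were examined, and 527 of the members were matched. The 31 lists with at least 4 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2. The preset inter-gene correlation was 0.01, and p-values were adjusted over the lists within each contrast. For each list, members were also counted with p-values adjusted over the list alone. The genes named in the text were chosen by a rule fixed at the same time. It took Ahr and Apoe, and the 6 largest rises and the 6 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap of the compared groups, leaving out gene models without an established name. It also took up to 4 members per list with the smallest p and the sex chromosome genes, and from these the text names a part, as some are not reported here. The interaction used the same rule without the overlap criterion.

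The library totals ran from 9794253 to 18924880 counts, so that 1 count was worth at most 0.102 CPM. Between 15882 and 16872 genes had at least 1 count in a library. A fold against a group with no counts was bounded with a floor of 3 counts over the group, and ratios to groups with 1 to 3 counts carry exact 95% intervals. Intervals and floors cover counting error only, since they were computed from counts summed over the libraries of a group. They hold no spread between mice. The reads also carry no molecular identifiers that are named in the sources used here. Replicate pairs were compared by a chi-square of their counts per degree of freedom, which lay between 22.2 and 248, so no pair was counted as 1 library.

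A list of 30 genes of neurons and glia was written after neural transcripts were seen in 2 libraries, control male replicate 1 and Ahr-null female replicate 1. It is given in CPM of the unscaled total. Each result was recomputed without these 2 libraries, an alternative chosen after seeing the data. The alternatives chosen beforehand were other scalings (RLE factors, library size alone, TMM without the 10 most abundant genes), other low-count filters, DESeq2 1.42.0, limma-voom, and limma on the authors' deposited values. They also included edgeR without robust estimation, 1 surrogate variable from sva 3.50.0, additive and genotype-only models, fits of part of the libraries, stricter thresholds, and leaving out each library in turn. Lists were also tested with an estimated correlation and with fry. Other splits of the libraries were fitted up to 100 times per contrast.

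The procedure was tested on simulated counts with 200 changed genes. They were drawn from the real mean of each gene over all libraries, the real library sizes and the real dispersions. Apart from the changed genes, no sex difference and no outlying library were built in, so the recovered shares need not hold for the real libraries. In a simulated genotype effect present in both sexes, over 13381 genes, 31.3% of the genes changed by 2-fold, 85.1% of those changed by 4-fold and 98.5% of those changed by 8-fold were recovered, and 7 of 150 calls were unchanged genes. In a simulated effect present only in males, over 13404 genes, the shares were 8.96%, 65.7% and 92.4%. For an effect only in females, over 13459 genes, they were 2.99%, 55.2% and 84.8%, and for a simulated sex difference in controls, over 13372 genes, 4.48%, 56.7% and 86.4%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.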

Results

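Gene expression was profiled by RNA-seq in the livers of 12 Apoe-/- mice, which lack apolipoprotein E, a carrier protein of plasma lipoproteins. In 6 of them the gene of the aryl hydrocarbon receptor, Ahr, a ligand-activated transcription factor, was also knocked out per the labels. The series asks how this receptor affects the liver. Each genotype held 3 males and 3 females, and all mice had 12 weeks on the diet labelled HFD. The total counts of replicates 1, 2 and 3 were 14914167, 13845303 and 14187427 in control males and 16612997, 15845965 and 14034820 in control females. They were 17363455, 13663243 and 16572159 in Ahr-null males and 9794253, 13372133 and 18924880 in Ahr-null females.

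The targeted gene Ahr (ENSMUSG00000019256, chromosome 12, 35497974 to 35535038, GRCm38) was not lower in the Ahr-null livers. Its mean level was 22.8 ± 2.3 CPM (SD, n = 3) in Ahr-null males against 20.2 ± 4.8 CPM in control males, and 16.5 ± 2.9 CPM against 15.6 ± 3.8 CPM in females. The averaged log2 fold change of Ahr was 0.13 ± 0.18 (SE; edgeR adjusted p = 0.7998). Counts over a whole gene cannot show the loss of an exon, and the alleles of Ahr and Apoe are not given in the sources used here, so neither gene's counts tested the genotype labels. The 2 Cyp1a genes described next did part the genotypes in each sex. Apoe was counted in all 12 libraries, at 73.3 to 215.2 CPM, with an averaged log2 fold change of -0.09 ± 0.25 (edgeR adjusted p = 0.906). Xist, the RNA that silences an X chromosome in females, reached 679 to 1292 CPM in 5 of the female libraries, 155 CPM in Ahr-null female replicate 1 and 2.33 to 13.3 CPM in the 6 male libraries. The Y-linked gene Kdm5d had 2.02 CPM in Ahr-null female replicate 1, 0 to 0.21 CPM in the other females and 5.21 to 8.61 CPM in males. For Eif2s3y, also Y-linked, these levels were 2.11, 0 to 0.98 and 29.55 to 47.5 CPM. They were 1.84, 0.12 to 2.51 and 37.8 to 71.98 CPM for Ddx3y, and 0.55, 0.06 to 0.44 and 5.27 to 9.75 CPM for Uty.

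Transcripts of neurons and glia stood out in 2 libraries. The 30 neural markers summed to 754.8 CPM in Ahr-null female replicate 1 and to 288.1 CPM in control male replicate 1, against 34.4 to 65.0 CPM in the other 10 libraries. Ahr-null female replicate 1 also had the highest level of Alb, the gene of serum albumin, with 55134 CPM against 6281 to 22047 CPM elsewhere. That library stood apart over all tested genes too. Its log2 CPM correlated at 0.805 and 0.811 with the other Ahr-null females, against 0.938 to 0.979 in the other replicate pairs. On the first principal component, with 35.8% of the variance, it lay at -136, against -17.8 to 27.8 in the other libraries. Why it stood apart was not tested. The 13 mitochondrially encoded genes took 56.6% ± 7.65 (SD, n = 6) of the counts in controls and 45.6% ± 10.9 in Ahr-null livers. In Ahr-null males the share was 38.9%, 52.7% and 30.4% in replicates 1, 2 and 3, against 46.7% to 57.3% in control males. Alb was singled out after its values were seen. The difference of -11.1 percentage points in the mitochondrial share had an exact two-sided permutation p = 0.0600 over 400 within-sex arrangements.

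**Figure D1:**
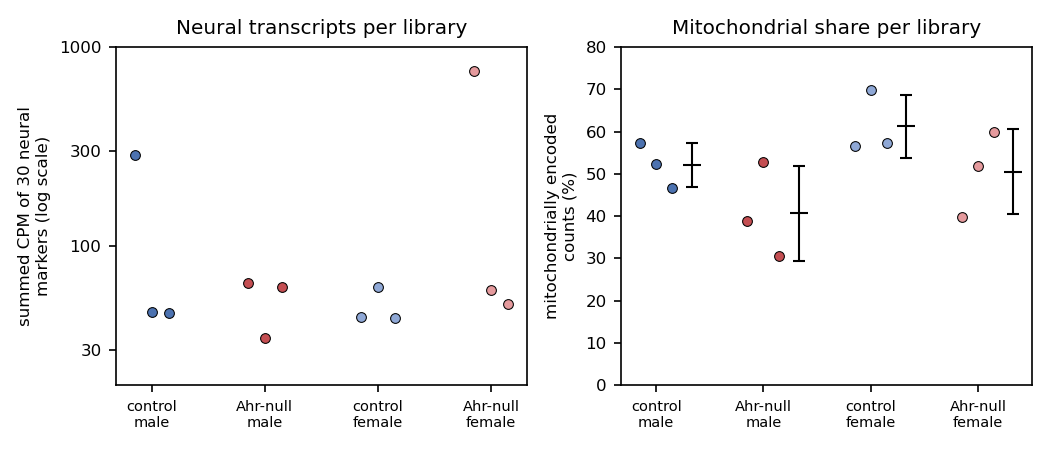
Summed level of 30 neural marker genes on a log axis (left, CPM of the unscaled total) and share of counts from mitochondrially encoded genes in percent (right) in the 12 livers, with a point per library and, on the right, the group mean ± SD of 3 libraries. Ahr-null female replicate 1 (754.8 CPM) and control male replicate 1 (288.1 CPM) lie above the other 10 libraries in the left panel.

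The main drug-metabolising target of the receptor was lower without Ahr in both sexes. Cyp1a2 (ENSMUSG00000032310, chromosome 9, 57676937 to 57683703), an enzyme that oxidises aromatic amines, had 946 ± 216 CPM (SD, n = 3) in control males and 123 ± 83.8 CPM in Ahr-null males. In females the levels were 591 ± 121 and 65.8 ± 31.5 CPM, and the averaged log2 fold change was -3.05 ± 0.36 (SE; edgeR adjusted p = 0.00663). Orm3, an orosomucoid gene of the acute phase, fell by 2.89 ± 0.32 on the log2 scale (adjusted p = 0.00578). Tff3, a trefoil peptide of mucus-producing epithelia, rose by 3.52 ± 0.45 (adjusted p = 0.00741). In each of these 3 genes every Ahr-null library lay beyond every control library of its sex. The p-values measure the spread between these 12 samples.

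In the AhR target battery, 2 of the 9 tested genes fell and 7 did not pass. These were Cyp1a2 and Cyp1a1, the latter at -2.45 ± 0.40 (adjusted p = 0.0148), and 1 gene was higher and 2 were lower when adjusted over the list alone. The list as a whole did not pass with camera (adjusted p = 0.186). Of the 10 pericentral hepatocyte genes, Glul, the glutamine synthetase of hepatocytes around the central vein, fell by 1.55 ± 0.24 (adjusted p = 0.0143), and 5 were lower when adjusted over the list alone. That list was lower (camera adjusted p = 1.27e-05, and adjusted p = 0.283 with an estimated correlation). In the list of CAR and PXR drug metabolism genes, 1 of 19 fell, Cyp2c54 at -2.09 ± 0.44 (adjusted p = 0.0424), while 2 were higher and 5 lower when adjusted over the list alone. The list was lower, at a camera adjusted p = 0.00147 and an adjusted p = 0.299 with an estimated correlation.

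Lipid and bile acid genes moved in both directions. Of 24 genes of cholesterol synthesis and SREBP2 targets, 2 rose and 22 did not pass. Mvd, an enzyme early in sterol synthesis, was among those that rose (1.41 ± 0.27, adjusted p = 0.0287). Adjusted over the list alone, 16 were higher and 1 lower, and the list was higher (camera adjusted p = 2.7e-07; adjusted p = 0.299 with an estimated correlation). Of 19 bile acid genes, Slc10a1 (-1.16 ± 0.22, adjusted p = 0.0275) and Slco1b2 (-1.33 ± 0.28, adjusted p = 0.0410), both uptake carriers of the hepatocyte, fell, and 4 were lower when adjusted over the list alone. The bile acid list was lower (camera adjusted p = 0.000446; adjusted p = 0.299 with an estimated correlation). Of 21 fatty acid synthesis genes, Thrsp (-2.50 ± 0.43, adjusted p = 0.0186) and Lpin1 (-1.19 ± 0.25, adjusted p = 0.0461) fell. Lpin1 lies on chromosome 12, the chromosome of Ahr, within 20 Mb of it. Adjusted over the list alone, 2 were higher and 4 lower, and the list did not pass (camera adjusted p = 0.145). Without the 2 libraries with neural transcripts it passed as lower (camera adjusted p = 0.0215; adjusted p = 0.472 with an estimated correlation). Vnn1, a pantetheinase, was the only 1 of 27 fatty acid oxidation and PPAR-alpha genes to pass, at -1.15 ± 0.20 (adjusted p = 0.0186), with 3 higher and 4 lower when adjusted over the list alone and a camera adjusted p = 0.708 for the list, whose median was 0.04 while camera ranked it as lower.

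Major urinary protein genes, which encode pheromone carriers made by the liver, gave most of the largest falls. Mup9, Mup1, Mup8, Mup13 and Mup2 had log2 fold changes of -3.83 ± 0.73, -3.75 ± 0.76, -3.68 ± 0.75, -3.15 ± 0.49 and -3.13 ± 0.50. Their copies are nearly identical, so the counts of each are uncertain and these falls are not separate results. In control male replicate 1, for example, Mup1 had 45314 counts and Mup8 45093. In males the fall was much smaller in replicate 2. Mup13 had 399, 1733 and 414 CPM in Ahr-null male replicates 1, 2 and 3, against 1776 to 4023 CPM in control males. Mup1 had 63.1, 880 and 39.1 CPM there, against 1063 to 3815 CPM. The female-biased liver genes were lower as a list (2 of 21 fell and 19 did not pass; 2 higher and 6 lower when adjusted over the list alone). The camera adjusted p was 0.000363, and the adjusted p = 0.299 with an estimated correlation. The members that fell, Sult3a1 and Sult2a1, are sulfotransferase genes whose values are given by sex further on. The male-biased list was ranked as lower by camera with a median of -0.04, 8 of 17 members having a positive fold change and none past the test (1 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.0191; adjusted p = 0.477 with an estimated correlation).

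Several lists of cell types other than hepatocytes were higher, with few members past the test. The T and NK cell list had no call among 10 members, nor any when adjusted over the list alone (camera adjusted p = 5.6e-05; adjusted p = 0.299 with an estimated correlation). Among 20 stellate cell and fibrosis genes Col5a2, a fibrillar collagen gene, rose by 1.17 ± 0.22 (adjusted p = 0.0277), and 1 was higher when adjusted over the list alone (camera adjusted p = 0.000272; adjusted p = 0.362 with an estimated correlation). The 11 cholangiocyte markers had no call in either count (camera adjusted p = 0.00199; adjusted p = 0.299 with an estimated correlation), and neither had the 7 red blood cell genes over all genes tested, with 2 higher when adjusted over the list alone (camera adjusted p = 0.00199, and 0.0539 without the 2 libraries with neural transcripts; adjusted p = 0.299 with an estimated correlation). Of 19 cell cycle genes Ccnd1, a cyclin of early G1, rose by 1.87 ± 0.40 (adjusted p = 0.0475), and 10 were higher when adjusted over the list alone (camera adjusted p = 3.25e-07; adjusted p = 0.299 with an estimated correlation). In Ahr-null male replicate 2 Ccnd1 had 2.71 CPM, within control males (1.78 to 6.57), against 12.9 and 13.6 CPM in replicates 1 and 3. Col5a2 too lay within control males there (4.73 CPM against 2.40 to 4.97, with 7.10 and 5.92 in replicates 1 and 3). Of 19 endoplasmic reticulum stress genes, Asns (3.49 ± 0.70, adjusted p = 0.0360) and Sdf2l1 (0.83 ± 0.17, adjusted p = 0.0381) rose, and 3 were higher when adjusted over the list alone (camera adjusted p = 0.0274; adjusted p = 0.299 with an estimated correlation). Asns had 3 counts in control females, and the ratio of Ahr-null to control females was 23.7 (95% interval 7.86 to 117.1). Of the counts in Ahr-null females, 56 were in replicate 1, which holds neural transcripts, and 11 and 24 in replicates 2 and 3. Marco, a scavenger receptor of macrophages, rose by 2.16 ± 0.34 (adjusted p = 0.0148), and Gpnmb, a gene of lipid-laden macrophages, fell by 1.64 ± 0.32 (adjusted p = 0.0337). Their lists did not pass: of 15 Kupffer cell genes 1 rose (1 higher when adjusted over the list alone; camera adjusted p = 0.761), and of 10 monocyte and lipid-associated macrophage genes 1 fell (2 lower when adjusted over the list alone; camera adjusted p = 0.489).

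Clock, immediate early and mitochondrial genes made up the other lists that were lower. Of 18 circadian clock genes, Bhlhe41 (-2.64 ± 0.34, adjusted p = 0.00741), Dbp (-2.53 ± 0.45, adjusted p = 0.0206) and Per3 (-1.57 ± 0.33, adjusted p = 0.0398) fell, and 2 were higher and 9 lower when adjusted over the list alone. Camera gave an adjusted p = 3.74e-05, and the adjusted p was 0.269 with an estimated correlation. In females alone Bhlhe41, Dbp and Per3 had log2 fold changes of -0.49, 0.22 and 0.01. None of these passed (edgeR adjusted p = 0.654, 0.900 and 0.995), so the averaged falls came mainly from the males. Dusp1, a phosphatase gene, was the only 1 of 10 immediate early genes to fall, at -1.31 ± 0.23 (adjusted p = 0.0196), and also the only 1 when adjusted over the list alone (camera adjusted p = 0.0215; adjusted p = 0.299 with an estimated correlation). No mitochondrially encoded gene of 13 passed in either count, yet all 13 had a negative fold change, and the list was lower (camera adjusted p = 5.49e-07, and adjusted p = 0.299 with an estimated correlation). The 13 genes are not independent, so their shared direction is not 13 separate observations. Their summed share per library gave an exact permutation p = 0.06, as given above. Among other genes that rose were H19 (3.53 ± 0.71), Gstm3 (2.30 ± 0.49), Cdc42ep5 (2.22 ± 0.46), Slc1a4 (2.12 ± 0.37) and Aldh1b1 (1.54 ± 0.32). The first 3 were near control levels in Ahr-null male replicate 2. There Gstm3 had 25.05 CPM (17.6 to 39.2 in control males, 198 and 289 in Ahr-null male replicates 1 and 3), H19 0.54 CPM (0.42 to 0.51, 2.64 and 8.64) and Cdc42ep5 5.89 CPM (0.67 to 3.70, 27.9 and 33.8). Saa3, a serum amyloid gene, fell by 2.16 ± 0.47, and with Orm3 was 1 of the 2 that fell among 25 acute phase genes (2 lower when adjusted over the list alone; camera adjusted p = 0.152, ranked as lower with a median of 0.01).

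Averaged over the sexes, 144 of 13641 genes passed the edgeR quasi-likelihood test, 72 higher and 72 lower, and 15 lists passed camera, of which 0 passed with an estimated correlation. Without the 2 libraries with neural transcripts 432 genes passed (207 higher and 225 lower), 128 of the 144 among them. In that fit 19 lists passed camera, 14 of the 15 among them, so some lists not called with all libraries were called there. In Ahr-null male replicate 2, 23 of the 144 lay within the range of control males, against 2 in each of replicates 1 and 3, and in the Ahr-null females 1 to 5 lay within that of control females. Of the genes named here, H19, Mup9, Mup1, Mup8, Aldh1b1 and Gstm3 lost their call when the 2 libraries with neural transcripts were left out. The count also moved with single libraries, to 663 without Ahr-null female replicate 1, 52 without Ahr-null female replicate 2, 6, 288 and 7 without Ahr-null male replicates 1, 2 and 3, 14, 14 and 17 without control female replicates 1, 2 and 3, and 71, 12 and 33 without control male replicates 1, 2 and 3. Cyp1a2, Orm3 and Tff3 passed under all 25 alternatives, including each of these 12 omissions. Scaling by library size alone raised the median log2 fold change of all genes by 0.50 and gave 986 genes higher and 67 lower. DESeq2 called 664 genes, the fit with 1 surrogate variable 1017 and the fit of genotype alone 80.

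**Figure D2:**
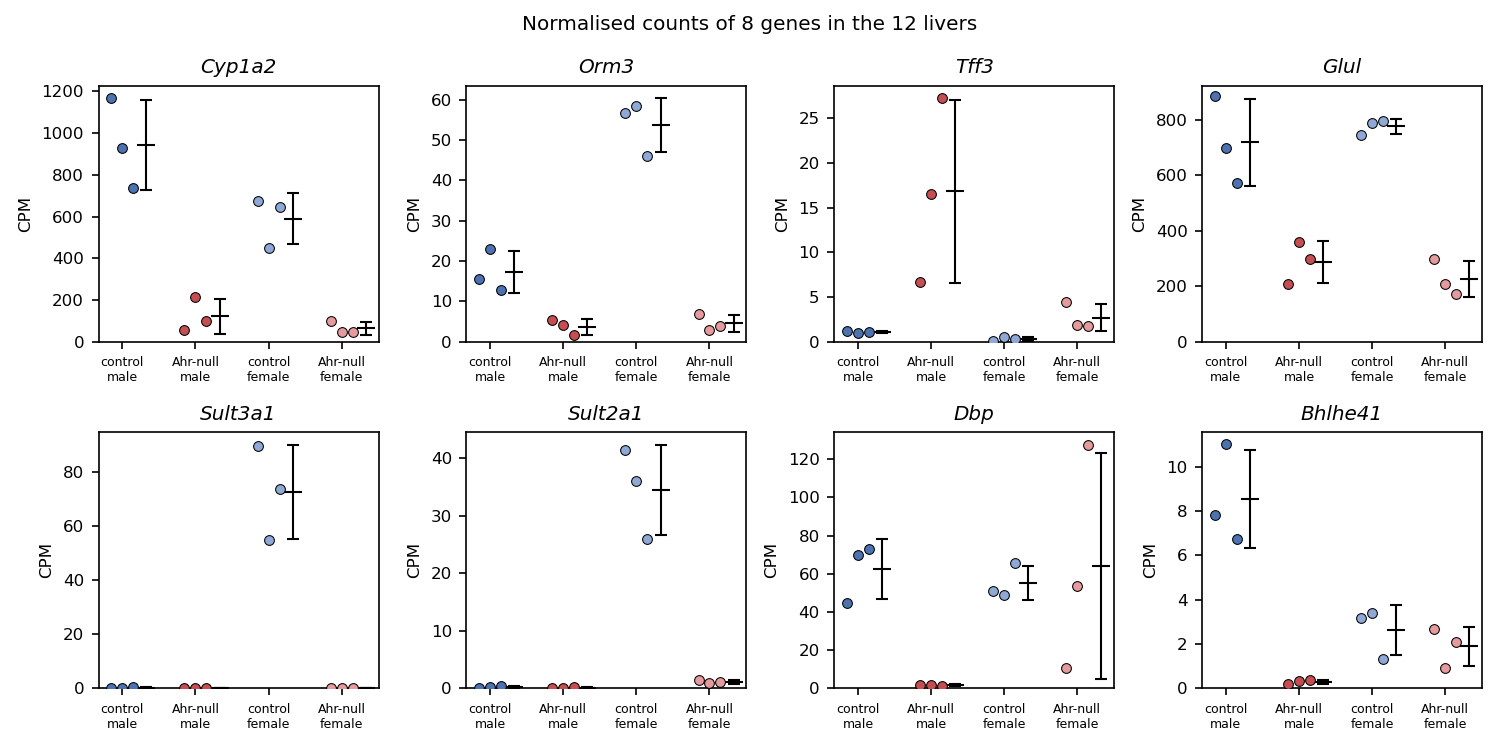
CPM of 8 genes in the 12 livers on linear axes from 0, with a point per library and the mean ± SD of each group of 3 beside it. Cyp1a2, Orm3 and Glul are lower and Tff3 higher in Ahr-null livers of both sexes, Sult3a1 and Sult2a1 are highest in control females, and Dbp and Bhlhe41 are low in Ahr-null males.

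In males circadian clock genes were among the few genes that passed the test over all genes. Dbp, a clock-controlled transcription factor, had 62.6 ± 15.8 CPM (SD, n = 3) in control males and 1.61 ± 0.540 CPM in Ahr-null males, a log2 fold change of -5.29 ± 0.73 (SE; edgeR adjusted p = 0.0235). Bhlhe41, a repressor of the clock, fell by 4.79 ± 0.53 (adjusted p = 0.00814). Cdkn1a, an inhibitor of the cell cycle, rose by 2.66 ± 0.34 (adjusted p = 0.0235) and Tff3 by 3.88 ± 0.58 (adjusted p = 0.0451), while Cyp46a1, a cholesterol hydroxylase, fell by 2.83 ± 0.38 (adjusted p = 0.0235). These 5 were all the genes that passed.

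Of the 18 clock genes 2 fell and 16 did not pass, but 3 were higher and 12 lower when adjusted over the list alone. Per3 had a log2 fold change of -3.15 ± 0.49 (edgeR adjusted p = 0.0582), and Arntl, which peaks opposite to Dbp in the daily cycle, of 1.64 ± 0.31 (adjusted p = 0.125). The CPM of 16 of the 18 did not overlap between Ahr-null and control males, and those of 0 of the 18 between the female groups, where chance gives 10% of genes, or 1.80. The clock genes are not independent and may part together, so the distance of 16 from 1.80 does not measure chance. The list was lower with camera (adjusted p = 2.77e-06; adjusted p = 0.126 with an estimated correlation). Control male replicate 1, with neural transcripts, was among the males. Without it and Ahr-null female replicate 1 the adjusted p of Dbp was 2.49e-05 and that of Per3 0.0239.

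**Figure D3:**
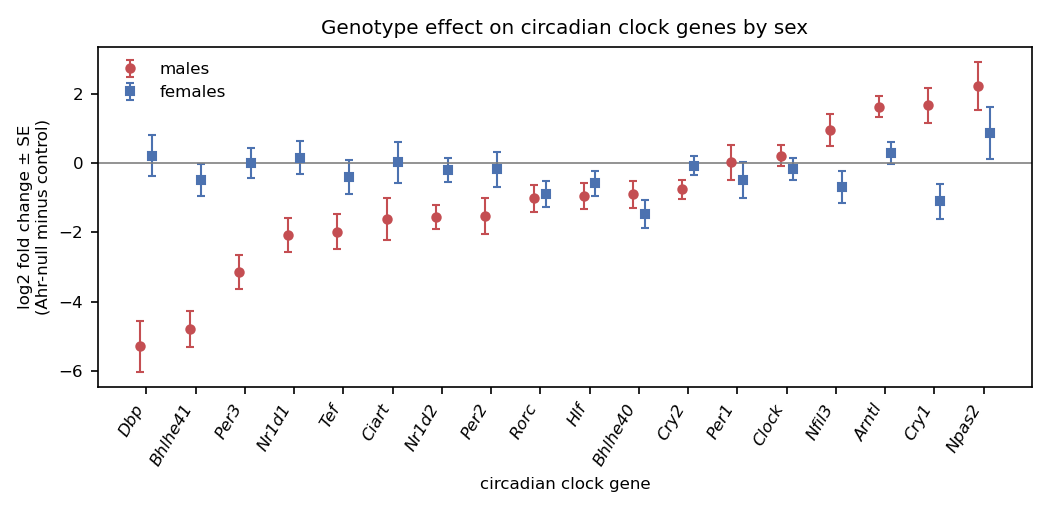
Log2 fold change ± SE of 18 circadian clock genes, Ahr-null minus control, in males (circles) and females (squares), ordered by the value in males. In males Dbp (-5.29), Bhlhe41 (-4.79) and Per3 (-3.15) lie lowest and Arntl (1.64) is among the genes above 0, while Dbp in females is at 0.22.

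The AhR target battery was lower as a list in males (0 of 9 passed; 1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.00391; adjusted p = 0.160 with an estimated correlation). Cyp1a2 had a log2 fold change of -2.94 ± 0.51 in males (edgeR adjusted p = 0.0987) and did not pass. Besides these 2 lists, camera ranked 5 as lower and 7 as higher, and with an estimated correlation the adjusted p of each called list was 0.126 to 0.454. The pericentral genes (median log2 fold change -0.75), mitochondrially encoded genes (-0.72), male-biased genes (-0.65), CAR and PXR genes (-0.40) and bile acid genes (-0.38) were lower. The mitochondrial share of Ahr-null male replicate 2 lay within that of control males, as given above. The red blood cell (1.66), cell cycle (1.12), B cell (0.95), cholesterol synthesis (0.88), cholangiocyte (0.54), T and NK cell (0.47) and endoplasmic reticulum stress genes (0.38) were higher. Some members lay within control males in Ahr-null male replicate 2, such as Cdc20 (0.47 CPM against 0.08 to 1.21) and Mvk (4.50 against 3.79 to 4.97). Others did not, such as Hba-a1 (140.8 against 23.9 to 97.0). No member of these 12 lists passed over all genes tested, and adjusted over the list alone 1 pericentral gene was lower and 1 cholesterol gene higher. Their camera adjusted p-values ran from 3.2e-07 for the mitochondrially encoded genes to 0.0243 for the endoplasmic reticulum stress genes. The T and NK cell and cholangiocyte lists did not pass once the 2 libraries with neural transcripts were left out (camera adjusted p = 0.576 and 0.180, medians 0.05 and 0.34). In that fit 18 lists passed camera, 12 of the 14 called with all libraries among them.

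In males 5 of 13641 genes passed the edgeR test, 2 higher and 3 lower. An unadjusted p under 0.05 was reached by 792, little above the share of 0.05 that chance alone gives. A fit of the male libraries alone called 25. With the 2 libraries that hold neural transcripts left out 27 passed (8 higher and 19 lower), the 5 among them. Leaving out Ahr-null female replicates 1, 2 and 3 gave 57, 3 and 8 genes, Ahr-null male replicates 1, 2 and 3 gave 0, 9 and 0, control female replicates 1, 2 and 3 gave 1, 3 and 1, and control male replicates 1, 2 and 3 gave 2, 0 and 1. With library size alone 7 were higher and 5 lower, and the median of all genes rose by 0.47.

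Several transcripts that mark the female liver fell in Ahr-null females, and Sult3a1 was nearly absent. Sult3a1 (ENSMUSG00000069668, chromosome 10, 33857721 to 33879532), a sulfotransferase gene, had 72.6 ± 17.3 CPM (SD, n = 3) in control females and 0.0368 ± 0.0638 CPM in Ahr-null females. It had 2681 counts in control females and 2 in Ahr-null females, a ratio of 1715 (95% interval 474.3 to 14168; edgeR adjusted p = 2.96e-05). Sult2a1 fell by 4.96 ± 0.46 (SE; adjusted p = 0.000571) and Sult2a2 by 3.44 ± 0.51 (adjusted p = 0.0405). Reads of these neighbouring Sult2a copies could be split between them, so their separate values are uncertain.

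These 3 were among the 4 of 21 female-biased genes that fell, and 17 did not pass, with 3 higher and 7 lower when adjusted over the list alone. The list was lower with camera (adjusted p = 4.73e-06; adjusted p = 0.375 with an estimated correlation). The median was -1.17, and 7 of the 21 members had a positive fold change. Mup13, Mup2, Mup14, Mup10 and Mup22 fell, with log2 fold changes of -4.57, -4.54, -4.44, -4.42 and -4.38 and standard errors of 0.72 to 0.76 (adjusted p = 0.0405 for each). They are again uncertain copies and not separate results. Mup20 of the same family had the other direction in females, at 63.9 to 97.2 CPM in controls and 186 to 681 CPM in Ahr-null livers, and did not pass (2.37 ± 0.46, adjusted p = 0.0748, or 0.0344 without the 2 libraries with neural transcripts). Mup13 went from 769 ± 271 CPM in control females to 32.4 ± 21.7 CPM. Orm3 fell by 3.57 ± 0.46 (adjusted p = 0.0110), Cyp1a2 by 3.17 ± 0.52 (adjusted p = 0.0405) and Dusp1 by 2.04 ± 0.34 (adjusted p = 0.0405). Fkbp11, a gene of protein folding, rose by 1.47 ± 0.23 (adjusted p = 0.0405) and Ccdc149 by 2.27 ± 0.38 (adjusted p = 0.0405).

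Of the acute phase genes, Orm3 fell and 24 did not pass (2 lower when adjusted over the list alone; camera adjusted p = 0.00265; adjusted p = 0.483 with an estimated correlation). Of the immediate early genes, Dusp1 fell and 9 did not pass (1 lower when adjusted over the list alone; camera adjusted p = 0.00265; adjusted p = 0.375 with an estimated correlation). Camera also called 11 other lists, and with an estimated correlation the adjusted p of each called list was 0.375 to 0.483. The other lists that were lower in females were the mitochondrially encoded (median log2 fold change -0.85), pericentral (-0.64), bile acid (-0.47), CAR and PXR (-0.47) and clock genes (-0.19). Those that were higher were the T and NK cell (1.53), red blood cell (1.19), cell cycle (1.06), cholesterol synthesis (0.98), cholangiocyte (0.93) and stellate cell genes (0.79). None of their members passed over all genes tested. Adjusted over the list alone, 3 cell cycle, 2 T and NK cell, 2 stellate cell, 2 cholesterol and 1 CAR and PXR gene were higher, and 3 CAR and PXR, 2 bile acid and 1 pericentral gene were lower. Their camera adjusted p-values ran from 8.48e-06 for cholesterol synthesis to 0.0255 for the clock. Leaving out the 2 libraries with neural transcripts ended the calls of cholesterol synthesis (camera adjusted p = 0.0595, median 0.41), red blood cell (0.303, median 0.99) and clock genes (0.267, median 0.03). The 14 lists became 7 without Ahr-null female replicate 2.

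In females 22 genes passed the edgeR test, 4 higher and 18 lower, and 3 passed in a fit of the female libraries alone. Without the 2 libraries with neural transcripts 235 passed (105 higher and 130 lower), the 22 among them. Leaving out Ahr-null female replicates 1, 2 and 3 gave 153, 3 and 5 genes, Ahr-null male replicates 1, 2 and 3 gave 4, 59 and 4, control female replicates 1, 2 and 3 gave 3, 3 and 3, and control male replicates 1, 2 and 3 gave 4, 4 and 4. Sult3a1 and Sult2a1 passed in each of these fits and in each of the other alternatives, 24 in all. With library size alone 96 were higher and 21 lower, and the median of all genes rose by 0.52.

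The test of the difference between the genotype effects of the sexes called 1 gene. For Sult3a1 the effect in males minus that in females was 10.39 ± 1.24 on the log2 scale (SE; edgeR adjusted p = 0.0202), but male livers held 0 to 6 counts in every library of either genotype, so a fall could not be measured in males and the size is uncertain. For Dbp the difference was -5.51 ± 0.92 (adjusted p = 0.208) and for Bhlhe41 -4.30 ± 0.68 (adjusted p = 0.199), so neither passed. For Sult2a1, with 0 to 5 counts in each male library, it was 3.80 ± 1.004 (adjusted p = 0.836). The female-biased list differed (1 of 21 higher; 8 higher when adjusted over the list alone; camera adjusted p = 1.32e-09; adjusted p = 0.523 with an estimated correlation), with the effect less negative in males. Of its 21 members, 10 had a mean under 1 CPM in control males, where a fall could hardly be seen. The acute phase (0 of 25; camera adjusted p = 0.000167), immediate early (0 of 10; adjusted p = 0.00616) and Kupffer cell lists (0 of 15; adjusted p = 0.0299) differed in the same direction. With an estimated correlation their adjusted p was 0.732, 0.556 and 0.732. The stellate cell list differed in the opposite direction (0 of 20; adjusted p = 0.00616; adjusted p = 0.970 with an estimated correlation). None of these 4 had a member past the test when adjusted over the list alone.

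In the interaction 628 of 13641 genes, the called one included, had an unadjusted p under 0.05. That is less than the share of 0.05 that chance alone gives. When the 2 libraries with neural transcripts were left out 4 genes passed, Dbp among them (adjusted p = 0.000119), and the stellate cell list had the other direction (adjusted p = 0.886). The count was 2 without Ahr-null female replicate 1, 1 without control male replicate 1 or 3, and 0 without each of the other 9 libraries. The 5 lists became 1 without Ahr-null female replicate 2 and 3 without control female replicate 3. With library size alone 1 gene was higher and 2 were lower. Over all tested genes the effects in males and females had a Pearson correlation of 0.23 and a Spearman correlation of 0.33 across genes, which are not independent replicates. These were 0.42 and 0.36 with the 2 libraries with neural transcripts left out.

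Of the 48 genes that differed between control males and females, 19 were on the 2 lists of genes known for sex bias in the mouse liver. Sult2a2 had 749 counts in control females and 0 in control males, at least 283-fold higher. Sult3a1 (-8.68 ± 0.63, edgeR adjusted p = 5.22e-05) and Sult2a1 (-7.24 ± 0.55, adjusted p = 5.22e-05) were lower in males. Cyp4a12a (6.27 ± 0.65, adjusted p = 0.000552), Mup20 (5.11 ± 0.52, adjusted p = 0.000552), Elovl3 (4.73 ± 0.53, adjusted p = 0.00101) and Cyp2d9 (4.53 ± 0.36, adjusted p = 5.76e-05) were higher in males. Of 17 male-biased genes 9 were higher in males (15 when adjusted over the list alone), and of 21 female-biased genes 10 were lower (18 when adjusted over the list alone). Both lists passed camera (adjusted p = 1.49e-43 and 5.91e-43) and had an adjusted p = 0.00496 with an estimated correlation, which was 0.0609 for each without the 2 libraries with neural transcripts.

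Other named genes lower in control males were Cyp3a41a (-8.26 ± 1.55), Cyp3a41b (-8.25 ± 1.57), Slc22a26 (-6.31 ± 0.68), Cyp2a22 (-5.45 ± 0.98) and Slc22a27 (-4.77 ± 0.80). The Cyp3a41 pair and the pair Cyp4a12a and Cyp4a12b (5.71 ± 0.68) are near-identical copies, so their separate values are uncertain. Of 19 endoplasmic reticulum stress genes, Sdf2l1 was higher in males (1.32 ± 0.25, adjusted p = 0.0426), with 7 higher when adjusted over the list alone (camera adjusted p = 4.27e-09; adjusted p = 0.0127 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, was the 1 of 19 bile acid genes higher in males (2.83 ± 0.44, adjusted p = 0.0114), with 3 when adjusted over the list alone (camera adjusted p = 0.00709; adjusted p = 0.490 with an estimated correlation). Alas2, the haem synthesis gene of red blood cells, was higher too (2.44 ± 0.40, adjusted p = 0.0190), as was Cyp2u1 (3.99 ± 0.44, adjusted p = 0.000835). The sex chromosome list passed (3 of 5 higher, Ddx3y at 5.32, Eif2s3y at 5.90 and Uty at 4.94, and Xist lower at -6.50; 4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 3.18e-07; adjusted p = 0.0371 with an estimated correlation). With the 2 libraries with neural transcripts left out, the estimated correlation gave an adjusted p = 0.115 for both the endoplasmic reticulum stress and the sex chromosome list.

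Lists of immune cells were lower in control males with no member past the test over all genes. All 15 Kupffer cell genes had a negative fold change (2 lower when adjusted over the list alone; camera adjusted p = 2.2e-07; adjusted p = 0.0530 with an estimated correlation). The interferon (adjusted p = 9.84e-06), mitochondrially encoded (0.000487), B cell (0.0202) and monocyte lists (0.0263) were lower and the cholesterol list (0.0294) higher, with no member past the test when adjusted over the list alone. Their adjusted p with an estimated correlation was 0.1504, 0.695, 0.262, 0.601 and 0.936 in that order. The B cell (0.213), monocyte (0.342) and cholesterol lists (0.0628) did not pass camera once the 2 libraries with neural transcripts were left out. In all 48 genes passed the edgeR test, 27 higher in males and 21 lower, and 79 (54 and 25) without the 2 libraries with neural transcripts, 44 of the 48 among them but not Slc22a27 (adjusted p = 0.119) or Cyp2a22 (adjusted p = 0.190). A fit of the control libraries alone called 189. The count was 101 without Ahr-null female replicate 1, 30 without Ahr-null male replicate 1, 19, 20 and 27 without control female replicates 1, 2 and 3, and 29, 22 and 24 without control male replicates 1, 2 and 3. With library size alone 47 were higher and 17 lower, and the median of all genes rose by 0.30.

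In Ahr-null mice the male-biased genes still differed between the sexes. Elovl3 (7.59 ± 0.62, edgeR adjusted p = 0.000133), Cyp2d9 (4.34 ± 0.36, adjusted p = 0.000133), Selenbp2 (3.84 ± 0.58, adjusted p = 0.0155) and Cyp7b1 (3.66 ± 0.46, adjusted p = 0.00455) were among the 8 of 17 male-biased genes higher in males (16 when adjusted over the list alone). The list passed camera (adjusted p = 1.47e-32; adjusted p = 0.0259 with an estimated correlation, or 0.135 when the 2 libraries with neural transcripts were left out). Of 21 female-biased genes 2 were lower in males, Sult2a2 and Sult2a1 (-3.44 ± 0.61, adjusted p = 0.0336), and 15 when adjusted over the list alone. Sult2a2 had 82 counts in females and 3 in males, a ratio of 38.1 (95% interval 12.6 to 188.5). The list was lower (camera adjusted p = 2.08e-14; adjusted p = 0.0588 with an estimated correlation). The clock genes Per3 (-4.005 ± 0.508, adjusted p = 0.00455) and Dbp (-5.33 ± 0.73, adjusted p = 0.00807) were lower and Arntl higher in males (1.95 ± 0.31, adjusted p = 0.0182), and 15 of 18 did not pass. With 4 higher and 6 lower when adjusted over the list alone, the clock list did not pass camera (adjusted p = 0.0820).

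Mup14 (4.75 ± 0.76), Mup13 (4.71 ± 0.75) and Mup2 (4.70 ± 0.76) were higher in Ahr-null males, as uncertain copies, and Slc22a26 was lower (-6.30 ± 0.73, edgeR adjusted p = 0.00286). The sex chromosome list passed (3 of 5 higher, Ddx3y at 6.12, Eif2s3y at 5.59 and Uty at 4.91, and Xist lower at -7.85; 4 higher and 1 lower when adjusted over the list alone; camera adjusted p = 4.58e-06; adjusted p = 0.0588 with an estimated correlation). Of 19 endoplasmic reticulum stress genes Sdf2l1 was higher (1.34 ± 0.24, adjusted p = 0.0349), with 6 when adjusted over the list alone (camera adjusted p = 1.14e-07; adjusted p = 0.0327 with an estimated correlation, or 0.135 when the 2 libraries with neural transcripts were left out). Besides these, 9 further lists passed camera and had an adjusted p of at least 0.255 with an estimated correlation. They were the bile acid, acute phase and immediate early genes, higher in males, and the T and NK cell, monocyte, stellate cell, cholangiocyte, interferon and mitochondrially encoded genes, lower in males. Of these, the stellate cell (camera adjusted p = 0.232), cholangiocyte (0.0778) and interferon lists (0.0772) did not pass with the 2 libraries with neural transcripts left out. In that fit 14 lists passed camera, 10 of the 13 called with all libraries among them, so some lists not called here were called there.

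In Ahr-null mice 38 genes passed the edgeR test between the sexes, 31 higher in males and 7 lower, and 110 (65 and 45) without the 2 libraries with neural transcripts, 37 of the 38 among them. A fit of the Ahr-null libraries alone called 0 genes with edgeR, where DESeq2 on all libraries called 226, and 1184 had an unadjusted p under 0.05 in the 12-library edgeR fit. The count was 90, 16 and 11 without Ahr-null female replicates 1, 2 and 3, 14 and 23 without Ahr-null male replicates 2 and 3, 14 and 18 without control female replicates 1 and 2, and 22 and 25 without control male replicates 2 and 3. Library size alone raised the median of all genes by 0.25.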

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

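The tests of the patterns weighed here, which are clock genes in males, female-biased transcripts in females and genes near Ahr, and the test of list members expressed in males were all chosen after the patterns were seen, while the other splits of the samples were planned.

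The genotype effect of Sult3a1 differed between the sexes by 10.39 on the log2 scale in the fitted model, by a test of the difference itself. Males held 0 to 6 counts in each library, so a fall could not be measured in them and the size is uncertain. The ratio in females alone had a 95% interval of 474.3 to 14168, which covers counting error only and no spread between mice. By the same kind of test 5 lists differed between the sexes: the female-biased genes (adjusted p = 1.32e-09), acute phase genes (0.0001673), Kupffer cell genes (0.0299), stellate cell genes (0.006158) and immediate early genes (0.006158). With an estimated correlation 0 of these 5 passed. In the female-biased list 10 of 21 members had a mean under 1 CPM in control males, which leaves little room for a fall. Of the other 11, 9 had a less negative or more positive effect in males (median difference 0.35, camera p = 0.000119, and p = 0.0708 with an estimated correlation, neither adjusted). Of 100 splits of the samples, 12 gave at least the 1 gene of the real interaction, the real split included. The highest other gave 33. The splits exchange genotype labels within each sex. A split that exchanges them mainly in 1 sex turns the averaged genotype effect into a difference between the sexes. These splits are therefore no test of chance for the interaction, and no conclusion is drawn from the 12 or the 33.

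Clock genes in Ahr-null males were weighed first. Neural RNA in control male replicate 1 is argued against, since the log2 fold change of Dbp was -5.481 without that library and Ahr-null female replicate 1. A difference in the time of day of collection may give the same picture as a changed clock. In 16 of 18 clock genes the male groups did not overlap, where chance gives 1.80, and Dbp and Arntl moved in opposite directions, which both explanations predict. As the 18 genes are not independent, 16 against 1.80 does not measure chance. Collection times are not given in the sources used here, so the time of day and the genotype cannot be told apart. The difference between the sexes for Dbp did not pass with all libraries (adjusted p = 0.208), and its adjusted p ran from 1.54e-06 to 0.871 over the alternatives.

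The loss of female-biased transcripts in Ahr-null females was weighed next. Neural RNA in Ahr-null female replicate 1 is argued against, as all 4 called members kept their call without the 2 libraries with neural transcripts. Male livers labelled female are argued against by Xist, whose lowest level in Ahr-null females was 11.66 times the highest in males. Some RNA of male origin in Ahr-null female replicate 1, where Kdm5d and Eif2s3y lay above the other females (2.02 and 2.11 CPM), Uty slightly so (0.55 CPM) and Ddx3y within them (1.84 CPM), was not excluded, though the 4 members kept their calls without it and the other library with neural transcripts. Fewer hepatocytes are argued against for the 4 called members only in that hepatocyte markers did not fall nearly as far. These 4 were picked because they passed the test, which favours large falls, so the size of their gap is not evidence by itself. The median of 13 hepatocyte markers lay above each of them by at least 3.471 on the log2 scale, with interquartile ranges of 0.765 with all libraries and 0.899 without the 2 with neural transcripts. In every Ahr-null female 3 of the 13 markers were higher than in every control female, and 0 were lower in this way. Chance alone parts 10% of genes in 1 direction or the other, so these 3 markers add little. For the list as a whole, whose median was -1.17, the test did not decide. The markers had a median of 0.02825 with all libraries (quartiles -0.24 and 0.52), a gap wider than their interquartile range. Without the 2 libraries their median was -0.36 and that of the list -1.22, a gap of 0.864 against 0.899, while over the list as tested in those 10 libraries, at -1.30, the gap would just have passed. These bounds were set after the first median was seen and changed since, so fewer hepatocytes stay open for the smaller falls of the list. An effect of the genotype on the liver's female pattern remains a hypothesis, and hormone levels were not measured here.

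Genes near Ahr were weighed last. A knockout can carry a segment of the donor strain around the targeted gene, and such a segment may bring its own expression differences. Within 20 Mb of Ahr on chromosome 12, 4 of 103 genes were called in the averaged effect, against 140 of 13538 elsewhere (odds ratio 3.87, 95% interval 1.02 to 10.4, two-sided Fisher's exact p = 0.02357). Without the 2 libraries with neural transcripts it was 6 of 103 against 426 of 13665 (odds ratio 1.92, interval 0.685 to 4.37, exact p = 0.142). The 2 intervals overlap. Another test left out Ahr-null female replicate 1 and counted genes without overlap between genotypes, 8 of 103 against 399 of 13538 (exact p = 0.0119). It is not counted as evidence, because that library was left out after Acp1, 1 of the 8, was seen at control level in it. Lpin1, which the report gives among the lipid genes, was 1 of the 4 called genes. Acp1 had also been seen before the first test and was 1 reason for it. Genotype effects on these genes themselves remain open, and strain was not tested from sequence.

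For the averaged effect chance is argued against but not excluded: of 100 splits, only the real one reached 144 genes, and the highest other gave 52. Without the 2 libraries with neural transcripts, only the real split of 100 reached 432, and the highest other gave 177. For the other contrasts the 10 splits are too few for a share under 0.05, with 1 split, the real one, reaching its count. The real value and the highest other were 5 and 0 in males, 22 and 1 in females, 48 and 0 between sexes in controls, and 38 and 0 between sexes in Ahr-null mice.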

How the results depend on the processing

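The fit without the 2 libraries with neural transcripts was chosen after seeing the data, and the other alternatives were planned. Of 106 gene results under 2789 alternatives, 2028 kept direction and side of the threshold, 715 lost the call, 37 gained it and 9 reversed. Of 72 list results under 1152 alternatives, 929 kept both, 222 lost the call and 1 reversed. The cause of these changes was not tested. A stricter threshold can only remove calls, while fits with fewer samples gave fewer calls in some cases and more in others.

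Without the 2 libraries with neural transcripts the averaged effect, males, females, the interaction, and the sex difference in controls and in Ahr-null mice gave 432, 27, 235, 4, 79 and 110 genes. In the same order, DESeq2 gave 664, 106, 491, 20, 142 and 226, and 1 surrogate variable 1017, 83, 264, 4, 116 and 142. An adjusted p under 0.01 left 8, 1, 3, 0, 25 and 12. For library size alone the first 4 were 1053, 12, 117 and 3. Limma-voom gave 3 in males and 35 in females. The deposited variance-stabilised values gave 9 in males, 46 in females and 4 in the interaction. Genotype alone gave 80 for the averaged effect, male libraries only 25, female libraries only 3, control libraries only 189 and Ahr-null libraries only 0 genes, where the 12-library edgeR fit gave 38 (1184 at an unadjusted p under 0.05). Beside the 0 of the interaction, 628 had an unadjusted p under 0.05, no more than chance alone gives.

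Leaving out 1 library gave 6 to 663 genes for the averaged effect, 0 to 57 in males, 3 to 153 in females, 0 to 2 in the interaction, 19 to 101 between the sexes in controls and 11 to 90 in Ahr-null mice. The lists called ran from 7 to 16 in females and 1 to 6 in the interaction. With an estimated correlation 0 lists passed in the averaged effect, males, females and the interaction, 4 between sexes in controls and 2 in Ahr-null mice. Fry gave 8, 1, 1, 0, 5 and 4.

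All 9 gene reversals were of Ahr or Apoe, which were not called. Averaged, Ahr became -0.00364 without the 2 libraries, and Apoe became 0.3561 with library size alone and 0.005046 without the 2 libraries. Leaving out 1 library moved Apoe between -0.2066 and 0.03994, above 0 without control male replicate 3, Ahr-null male replicate 3 or Ahr-null female replicate 1. In females Ahr became -0.03889 without the 2 libraries, and -0.068 to 0.2703 when 1 library was left out, below 0 without control female replicate 3 or Ahr-null female replicate 1. The stellate cell list reversed in the interaction without the 2 libraries (adjusted p = 0.8856). In the simulation most 2-fold changes were missed at this depth and number of samples.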

Other observations

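The tests of the neural transcripts were chosen after these were seen.

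The neural transcripts came with 25 of the 30 markers higher in both Ahr-null female replicate 1 and control male replicate 1 than in every other library. That is consistent with RNA of nervous tissue, or with reads of another library, and these sources were not told apart by a test. The excess in the former was 3.10 times that in the latter in the median marker (interquartile range 2.84 to 3.44), with a Spearman correlation of 0.974 across markers, which are not independent. Of the 30 markers, 21 were under 1 CPM in the median of the other libraries. Genotype as the cause is argued against only by the values that define the pattern, as 0 of the other Ahr-null libraries held over 100 CPM while a control library did.

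Lists not described above had no call in the averaged effect with camera, with adjusted p-values of 0.137 for NRF2 targets (1 of 22 rose) and interferon genes (0 of 21), 0.138 for lipoprotein genes (0 of 24) and periportal hepatocyte genes (1 of 12 rose), 0.0889 for glucose metabolism (0 of 15), 0.323 for the tryptophan pathway (0 of 9), 0.0708 for B cells (0 of 7), and 0.708 for sinusoidal endothelium (0 of 15) and hepatocyte markers (0 of 13). Adjusted over the list alone, 2 NRF2, 2 tryptophan and 1 periportal gene were higher. The lipoprotein list was among those called only without the 2 libraries with neural transcripts, as lower (camera adjusted p = 0.0181; adjusted p = 0.434 with an estimated correlation). The neutrophil and adipocyte lists had 3 tested members each and the exocrine pancreas list 0, so they were not tested.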
